A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

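Ends of polyadenylated RNA were measured in 12 libraries of yeast strain JGY2000, 2 DMS-treated and 2 mock-treated (noDMS) replicates in each of 3 media. The labels describe duplicate cultures per medium, Schizosaccharomyces pombe cells added as an internal control, and Bowtie as the aligner, with no version. The labels do not say that a letter (A or B) joins libraries across media or treatments. In the files, residuals of libraries that share a letter correlated across genes with r between -0.04 and 0.14, so letters were not used as a block in the fits. DMS and noDMS libraries of the same medium and letter were still combined into a sample for averages and ratios, a match that neither labels nor values establish.

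In the library files the authors give, for each 3′ end, its 5′ ends with values scaled to 20 M reads per library. The file names give the factor, and 100.0% of values up to 100 reads were whole reads times that factor, within 0.006 or a share of 0.0005. In the deposited tables per medium, the signal is the number of DMS reads per isoform of both replicates together, scaled by the authors to 40 M reads. These tables also give isoform half-lives, with no time unit or medium per the file headers. In the deposited table of all conditions, each score is the authors' DMS minus noDMS difference in scaled reads at an A or C of an isoform, over both replicates, with negative differences set to 0. That table also holds YPD, whose libraries were not analysed here. The genome build is not stated in the files, so no coordinates are given. Which base the deposited 5′ end denotes is not stated either. The authors' scores are blank at G and U when the deposited 5′ end is taken as the base, so that base was used for reactivity.

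Each 3′ end was assigned to the gene with the nearest reading-frame end upstream on the same strand, up to 400 bases away. This gave the same gene and distance as the deposited tables for 99.9% of their isoforms. The tables name 5750 genes, of which 5450 of 5453 protein-coding ones matched a locus tag of the reference. A gene's value is its sum of scaled reads. Fits used log2 of the value plus 10, for genes with a mean of at least 50 over the 12 libraries, and fold changes of genes near 10 scaled reads depend on that pseudocount. For comparisons of media the DMS and noDMS libraries of a medium and letter were averaged, giving n = 2 per medium and 6 samples, and limma with a trend and Benjamini-Hochberg adjustment at 0.05 was run on all 3 media together. DMS was compared with noDMS over 12 libraries with medium as a block. An interaction of DMS with medium was added. Of 35 gene lists written before the data were examined, 33 had at least 3 measured members. They were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it. The comparisons, tests and most of the other settings were fixed then too. Named genes are the 10 highest and 10 lowest past the threshold whose replicates do not overlap, up to 4 members per list, the 5 genes with the lowest and the 5 with the highest mean r of isoform profiles between media, and the marker genes of the strain.

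Reactivity was the log2 ratio of DMS to noDMS values plus 10 at A and C positions within 400 bases of the main 3′ end with a mean of at least 20, minus the gene's median, fitted with limma. After the data were seen, 482 of 65188 positions with no spread at all were left out, because with them the moderation of the spread recovered nothing in simulated data; 0 positions passed with or without them. The planned test of bases used the base just upstream of the deposited 5′ end, and the base at the deposited 5′ end was the second choice listed then. Profiles were compared by r in genes with at least 10 positions. Pooled profiles used the last 317 bases. In the deposited Minimal block, the blanks of 5899 of 14942 isoform lines (39.5%) did not match the isoform's sequence, and 5629 of these had an r over 0.9 to another isoform of the gene. The Minimal profiles were therefore rebuilt from the libraries, and 6532 columns of single replicates in that table were not used.

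Shares at bases were compared by exact permutation within media, over 216 arrangements with a smallest p of 0.00926, and differences over 6 samples by exact sign flips, all two-sided. With 2 replicates per group, p-values rest on a spread shared between media. Depth ran from 8864664 to 27627022 reads and from 9.91 to 42.7 reads per distinct pair of ends, so reads include PCR copies and are not independent molecules. In simulated data limma recovered 37%, 37% and 36% of genes changed by log2 1, and 77%, 82% and 86% of those changed by log2 2, in YPGal against Sorbitol, Minimal against Sorbitol and Minimal against YPGal, with 4, 5 and 4 unchanged genes called. For positions, changes of log2 2, 4 and 8 were recovered in 0% of cases when noise had the raw spread per position, and in 0%, 8% and 87.5% in YPGal against Sorbitol when it had the spread limma estimated. The bounds of the tests of explanations and the windows of the distance test were set after their values were seen. Alternatives covered pseudocounts, filters, TMM scaling, edgeR and DESeq2 on whole reads, noDMS or DMS libraries alone, 12 libraries with DMS as a covariate, a replicate block and each replicate left out. Distinct end pairs, centring on distance, the base next upstream, G and U positions for profiles, and deposited Minimal profiles were added after the data were seen. Tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.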

Results

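Ends of polyadenylated RNA were sequenced in 12 libraries of the yeast Saccharomyces cerevisiae, strain JGY2000, whose largest RNA polymerase II subunit can be removed from the nucleus with rapamycin. Cells grew in 3 media: rich medium with 2% galactose (YPGal), a dextrose medium with few amino acids (Minimal), and rich dextrose medium with 1 M sorbitol (Sorbitol). In each medium 2 replicates were treated with 500 µl of dimethyl sulphate (DMS) for 2 min and 2 were mock-treated (noDMS). DMS modifies A and C bases that are not paired, and reverse transcription stops at a modified base, so an excess of 5′ ends in DMS libraries marks a reactive base. The 3′ end of each read names the poly(A) site, and with it the 3′ isoform. Libraries held 8864664 to 27627022 reads on 345896 to 1007330 distinct pairs of a 3′ end and a 5′ end. Between 90.6% and 94.0% of reads were assigned to a gene, and log2 gene values of the 2 replicates of a group correlated across genes with r between 0.939 and 0.959. Genes are not independent replicates. Cells of Schizosaccharomyces pombe, added to every culture as an internal control, gave 1.95% ± 0.158 of noDMS reads in YPGal, 1.00% ± 0.115 in Minimal and 0.322% ± 0.0029 in Sorbitol (mean and SD, n = 2 each). Gene values below are reads scaled to the same total in each library, so they compare RNAs within the total and not per cell.

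The comparison of YPGal with Sorbitol addressed which RNAs differed between growth on galactose and growth on dextrose under osmotic pressure. Genes of galactose use rose most. GAL1, the galactokinase that starts galactose breakdown, stood at 224920 scaled reads in YPGal and 422 in Sorbitol, a log2 difference of 9.19 ± 0.29 (limma adjusted p = 1.69e-12; errors after log2 values are SE, n = 2 per medium). The permease GAL2, the transferase GAL7 and the epimerase GAL10 rose by 9.51 ± 0.41, 9.43 ± 0.37 and 9.06 ± 0.21. The largest decreases were in HXT1, a low-affinity glucose transporter, which fell by 7.54 ± 0.27 from 7853 to 33.7 scaled reads, and in ADE17, an enzyme of purine synthesis, which fell by 5.18 ± 0.17 from 28163 to 813. With limma, 846 of 5416 genes passed at an adjusted p of 0.05, 431 of them higher and 415 lower in YPGal, and 274 rose and 274 fell more than 2-fold. The replicates of the media did not overlap for 3085 genes (57.0%, against 33.3% by chance). With the noDMS libraries alone 305 genes passed, and without Sorbitol replicate B 333.

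Of 10 genes of galactose use 9 rose and 1 fell, with a median log2 difference of 4.49 (9 and 1 adjusted over the list alone; camera adjusted p = 1.67e-18, and adjusted p = 0.0849 with an estimated correlation). The regulator GAL3 rose by 5.00 ± 0.51 and the reductase GCY1 by 3.98 ± 0.21. Respiratory chain and ATP synthase genes rose together: 30 of 35 rose, 2 fell and 3 did not pass (32 and 2 adjusted over the list alone, median 1.30; camera adjusted p = 1.58e-22). This list passed with an estimated correlation too (adjusted p = 0.0437). CYC1, the main cytochrome c, rose by 2.35 ± 0.19 to 11688 scaled reads, and the NADH dehydrogenase NDE1 by 1.87 ± 0.20. The members that fell were CYC7 and COX5B, the low-oxygen forms of cytochrome c and of a cytochrome oxidase subunit, by 2.07 ± 0.40 and 1.75 ± 0.25. Of 17 TCA cycle genes 7 rose and 10 did not pass (8 rose adjusted over the list alone, median 0.38; camera adjusted p = 1.76e-05, and adjusted p = 0.174 with an estimated correlation). The succinate dehydrogenase subunits SDH2, SDH1 and SDH4 rose by 1.72 ± 0.22, 1.53 ± 0.33 and 1.25 ± 0.20.

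Glycolytic and fermentative genes fell in YPGal: 13 of 22 fell and 9 did not pass (17 fell adjusted over the list alone, median -0.96; camera adjusted p = 1.19e-15, and adjusted p = 0.113 with an estimated correlation). TDH2, a glyceraldehyde-3-phosphate dehydrogenase, fell by 2.23 ± 0.17, PGK1 by 2.13 ± 0.17 and the enolase ENO1 by 1.93 ± 0.18. Among 9 hexose transporters 1 rose and 3 fell, and the list did not pass (camera adjusted p = 0.193). HXT3 fell by 4.50 ± 0.24, and the high-affinity transporter HXT6 rose by 2.92 ± 0.36, an average of 4.67 in the noDMS and 1.17 in the DMS libraries, which differed (limma interaction adjusted p = 0.0364). HXT4 fell by 1.44 ± 0.45, but with the noDMS libraries alone its difference was 0.06 and did not pass. Of 18 purine and one-carbon genes 14 fell and 1 rose (15 and 1 adjusted over the list alone, median -1.95; camera adjusted p = 3.78e-19, and adjusted p = 0.0849 with an estimated correlation). The glycine cleavage genes GCV1 and GCV2 fell by 3.90 ± 0.21 and 3.23 ± 0.21, and ADE2 by 2.94 ± 0.21. Phosphate starvation genes rose, 11 of 14 with 3 not passed (11 adjusted over the list alone, median 1.52; camera adjusted p = 4.51e-10, and adjusted p = 0.0849 with an estimated correlation). SPL2, a regulator of phosphate uptake, rose by 4.50 ± 0.44, and the phosphate transporter PHO84 by 2.67 ± 0.58 to 11610 scaled reads.

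Osmotic and stress genes were lower in YPGal than in Sorbitol. Of 23 genes of glycerol and the osmotic response 11 fell and 1 rose (12 and 1 adjusted over the list alone, median -1.15; camera adjusted p = 3.13e-06, and adjusted p = 0.225 with an estimated correlation). GPD1 and GPP2, which make glycerol, fell by 3.18 ± 0.27 and 2.91 ± 0.19, and the glycerol importer STL1 by 2.82 ± 0.56. The member that rose was the kinase gene MRK1, by 4.38 ± 0.55. General stress genes fell, 15 of 22 with 7 not passed (17 adjusted over the list alone, median -1.28; camera adjusted p = 5.81e-11, and adjusted p = 0.238 with an estimated correlation). The chaperone HSP26 fell by 3.09 ± 0.25, the membrane protein HSP12 by 3.05 ± 0.30 and HSP42 by 2.69 ± 0.50. The median of this list was -0.56 in the noDMS libraries and -2.02 in the DMS libraries. Of 16 trehalose and glycogen genes 7 fell and 9 did not pass (7 adjusted over the list alone, median -0.66; camera adjusted p = 1.18e-05, and adjusted p = 0.317 with an estimated correlation). The median of that list was -0.38 in the noDMS libraries, where 6 of 16 members were higher, and -1.16 in the DMS libraries, where 15 were lower. The trehalose synthase subunits TSL1 and TPS2 fell by 2.57 ± 0.27 and 1.97 ± 0.32.

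Growth and mating genes moved as well. Of 30 ribosome biogenesis genes 16 rose and 14 did not pass (21 rose adjusted over the list alone, median 0.85; camera adjusted p = 5.06e-11, and adjusted p = 0.367 with an estimated correlation). The RNA helicase DBP2 rose by 2.02 ± 0.32 and the nucleolar protein NSR1 by 1.65 ± 0.25. Of 28 cell wall genes 10 fell and 1 rose (12 and 1 adjusted over the list alone, median -0.18; camera adjusted p = 0.0062, and adjusted p = 0.199 with an estimated correlation). The mannoproteins CWP1 and CWP2 fell by 3.41 ± 0.22 and 1.55 ± 0.21. Of 11 genes of MATa and general mating 4 fell and 7 did not pass (7 fell adjusted over the list alone, median -0.70; camera adjusted p = 0.000137, and adjusted p = 0.129 with an estimated correlation). The agglutinin gene AGA1 fell by 1.52 ± 0.25 and the pheromone gene MFA2 by 0.89 ± 0.16. WSC4, a sensor of cell wall stress, fell by 4.29 ± 0.32, and SHM2, a serine hydroxymethyltransferase, by 3.53 ± 0.16.

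The comparison of Minimal with Sorbitol set a dextrose medium with few amino acids against rich dextrose medium with 1 M sorbitol. Amino acids, other nutrients and osmotic pressure differ together here, so their effects cannot be told apart. Amino acid synthesis genes rose most. ARG1, which makes argininosuccinate, stood at 30239 scaled reads in Minimal and 348 in Sorbitol, a log2 difference of 6.45 ± 0.29 (limma adjusted p = 6.87e-10; SE, n = 2 per medium). ARG3 of the same pathway rose by 5.79 ± 0.50, and the vitamin B6 genes SNO1 and SNZ1 by 4.77 ± 0.70 and 3.58 ± 0.24. STL1, the glycerol importer, fell by 6.34 ± 0.56 from 1335 to 7.80 scaled reads, and HSP12 by 5.63 ± 0.30 from 16280 to 356. With limma 502 of 5416 genes passed, 197 higher and 305 lower in Minimal, and 114 rose and 218 fell more than 2-fold. The replicates did not overlap for 3003 genes (55.4%, against 33.3% by chance). The median log2 difference of all tested genes was -0.14 here and -0.14 in Minimal against YPGal, and -0.01 and 0.00 after TMM scaling, which gave 263 higher and 238 lower. Beside these 502 genes, 253 passed with the noDMS libraries alone, 245 with the DMS libraries alone, 210 without Minimal replicate A and 204 without Sorbitol replicate B.

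Of 10 arginine genes 8 rose and 2 did not pass (10 rose adjusted over the list alone, median 2.94; camera adjusted p = 8.8e-24, and adjusted p = 0.0922 with an estimated correlation). ARG5,6 rose by 3.32 ± 0.28. Of 9 lysine genes 8 rose and 1 did not pass (8 rose adjusted over the list alone, median 2.28; camera adjusted p = 5.63e-21, and adjusted p = 0.0922 with an estimated correlation), among them LYS9 by 3.30 ± 0.19, LYS20 by 3.27 ± 0.21 and LYS1 by 3.14 ± 0.20. Of 11 genes of leucine, isoleucine and valine synthesis 8 rose and 3 did not pass (8 rose adjusted over the list alone, median 1.21; camera adjusted p = 2.48e-13, and adjusted p = 0.141 with an estimated correlation), such as ILV2 by 1.81 ± 0.20. Of 6 histidine genes 2 rose and 4 did not pass (4 rose adjusted over the list alone, median 0.68; camera adjusted p = 4.02e-05, and adjusted p = 0.187 with an estimated correlation), and HIS4 rose by 1.24 ± 0.20. Of 14 aromatic amino acid genes 6 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.67; camera adjusted p = 4.35e-06, and adjusted p = 0.199 with an estimated correlation). ARO3 rose by 1.29 ± 0.22, while ARO9, a transaminase of aromatic amino acid breakdown, fell by 5.14 ± 0.23, and ARO10, the next enzyme of that route and outside the list, by 5.27 ± 0.36. Of 21 genes of threonine, serine, glycine and glutamate synthesis 6 rose and 1 fell (9 and 2 adjusted over the list alone, median 0.30; camera adjusted p = 4.35e-06, and adjusted p = 0.141 with an estimated correlation), with SER3 up by 2.92 ± 0.32 and the glutamate dehydrogenase GDH1 by 1.71 ± 0.18.

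Metal and phosphate genes moved in both directions. The zinc regulon had 3 of 8 genes higher and 5 not passed (3 rose adjusted over the list alone, median 0.57; camera adjusted p = 0.000248, and adjusted p = 0.181 with an estimated correlation). The zinc transporters ZRT1 and ZRT2 rose by 3.88 ± 0.29 and 1.366 ± 0.20. Of 22 iron and copper genes 8 fell and 14 did not pass (11 fell adjusted over the list alone, median -1.01; camera adjusted p = 1.2e-06, and adjusted p = 0.187 with an estimated correlation). The reductase FRE1, the copper transporter CTR1 and the mannoprotein FIT3 fell by 3.19 ± 0.25, 2.71 ± 0.21 and 2.36 ± 0.20. Of 14 phosphate starvation genes 5 fell and 9 did not pass (5 fell adjusted over the list alone, median -0.42; camera adjusted p = 0.00396, and adjusted p = 0.187 with an estimated correlation), with PHO84 down by 5.70 ± 0.58 and SPL2 by 3.20 ± 0.44.

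Stress and reserve genes were lower in Minimal than in Sorbitol. Of 22 general stress genes 11 fell and 11 did not pass (16 fell adjusted over the list alone, median -1.13; camera adjusted p = 8.92e-11, and adjusted p = 0.187 with an estimated correlation). HSP26 fell by 2.39 ± 0.25 and YGP1, a glycoprotein of starved cells, by 2.13 ± 0.30. Of 16 trehalose and glycogen genes 11 fell and 5 did not pass (15 fell adjusted over the list alone, median -1.17; camera adjusted p = 2.39e-11, and adjusted p = 0.187 with an estimated correlation), among them the glycogen phosphorylase GPH1 by 2.85 ± 0.27. Of 23 osmotic genes 8 fell and 1 rose (11 and 1 adjusted over the list alone, median -0.91; camera adjusted p = 6.36e-07, and adjusted p = 0.187 with an estimated correlation), with ALD3 down by 3.15 ± 0.32 and GPP2 by 3.05 ± 0.19. Of 30 ribosome biogenesis genes 7 rose and 23 did not pass (17 rose adjusted over the list alone, median 0.59; camera adjusted p = 6.13e-12, and adjusted p = 0.311 with an estimated correlation). Respiratory chain genes did not pass as a list (camera adjusted p = 0.8294), and RIP1, the Rieske protein, rose by 1.140 ± 0.34 in all libraries but had -0.19 with the DMS libraries alone, which did not pass.

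The comparison of Minimal with YPGal set a dextrose medium with few amino acids against rich galactose medium. GAL1 stood at 347 scaled reads in Minimal and 224920 in YPGal, a log2 difference of -9.34 ± 0.29 (limma adjusted p = 1.32e-12; SE, n = 2 per medium). GAL7, GAL2 and GAL10 fell by 10.81 ± 0.37, 10.04 ± 0.41 and 9.78 ± 0.21, and the phosphate gene PHO84 by 8.37 ± 0.58. ARG1 rose by 7.73 ± 0.29, ARG3 by 7.65 ± 0.50, and the glucose transporters HXT1 and HXT3 by 6.94 ± 0.27 and 5.11 ± 0.24. ADE17 rose by 4.43 ± 0.17 and MIG2, a repressor in the glucose response, by 4.26 ± 0.35. The value for MIG2 averaged 2.37 in the noDMS and 6.15 in the DMS libraries, which differed (limma interaction adjusted p = 0.00845). In the YPGal DMS libraries MIG2 lay at the floor, log2 3.322 for the pseudocount of 10 alone. The DMS value and the interaction therefore depend on that pseudocount. With limma 805 of 5416 genes passed, 303 higher and 502 lower in Minimal (182 and 287 more than 2-fold), and TMM scaling gave 421 and 365. The replicates did not overlap for 3076 genes (56.8%, against 33.3% by chance). With the noDMS libraries alone 455 genes passed, without YPGal replicate B 520 and without Minimal replicate A 388.

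In Minimal against YPGal, 7 lists passed with an estimated correlation too, each at adjusted p = 0.0453. All 10 genes of galactose use fell (10 adjusted over the list alone, median -5.10; camera adjusted p = 4.01e-21). Of 35 respiratory genes 30 fell and 1 rose (33 and 1 adjusted over the list alone, median -1.38; camera adjusted p = 6.19e-22), with CYC1 down by 2.40 ± 0.19 and the internal NADH dehydrogenase NDI1 by 1.80 ± 0.26. Phosphate starvation genes fell, 10 of 14 with 4 not passed (10 adjusted over the list alone, median -2.27; camera adjusted p = 1.42e-11), among them PHM6 by 4.19 ± 0.33. Of 18 purine and one-carbon genes 15 rose and 3 did not pass (15 rose and 1 fell adjusted over the list alone, median 1.89; camera adjusted p = 1.6e-22), with GCV1 up by 3.41 ± 0.21. Arginine genes rose, 8 of 10 (9 adjusted over the list alone, median 2.75; camera adjusted p = 1.57e-17), and lysine genes, 8 of 9 (8 adjusted over the list alone, median 2.14; camera adjusted p = 7.26e-16), such as LYS1 by 3.44 ± 0.20. Of 21 genes of threonine, serine, glycine and glutamate synthesis 11 rose and 2 fell (12 and 3 adjusted over the list alone, median 0.75; camera adjusted p = 1.98e-07), with SHM2 up by 3.10 ± 0.16.

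Glycolytic genes rose in Minimal against YPGal, 15 of 22 with 1 lower (18 and 1 adjusted over the list alone, median 1.03; camera adjusted p = 9.57e-16, and adjusted p = 0.0714 with an estimated correlation). PGK1 rose by 2.13 ± 0.17, while the hexokinase HXK1 fell by 2.19 ± 0.20, with -3.17 in the noDMS and -1.22 in the DMS libraries (limma interaction adjusted p = 0.0367). Of 6 histidine genes 5 rose (5 adjusted over the list alone, median 1.12; camera adjusted p = 2.65e-08, and adjusted p = 0.0946 with an estimated correlation), HIS4 by 3.30 ± 0.20. TCA cycle genes split, 4 higher and 9 lower of 17 (4 and 10 adjusted over the list alone, median -0.65; camera adjusted p = 0.0473, and adjusted p = 0.324 with an estimated correlation). The members that rose included CIT2, by 2.35 ± 0.27, which serves glutamate synthesis, and SDH2 fell by 2.23 ± 0.22. Of 11 mating genes 4 rose (5 adjusted over the list alone, median 0.59; camera adjusted p = 6.34e-05, and adjusted p = 0.0777 with an estimated correlation). General stress genes did not pass as a list (median -0.12, camera direction up, adjusted p = 0.844), and its median differed in sign between the agents: the list was lower in the noDMS libraries alone (median -0.82; camera adjusted p = 0.000332), while in the DMS libraries the median was 0.63 with 18 of 22 members higher. The difference between the agents passed with camera at the preset correlation (adjusted p = 7.24e-13) but not with an estimated one (adjusted p = 0.478). HSP12 fell by 2.57 ± 0.30 and the chaperone SSA2 rose by 2.02 ± 0.19, with 1.065 in the noDMS and 2.98 in the DMS libraries (limma interaction adjusted p = 0.0211). HSP42 rose by 1.53 ± 0.50 but had -0.68 with the noDMS libraries alone, which did not pass.

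**Figure D1:**
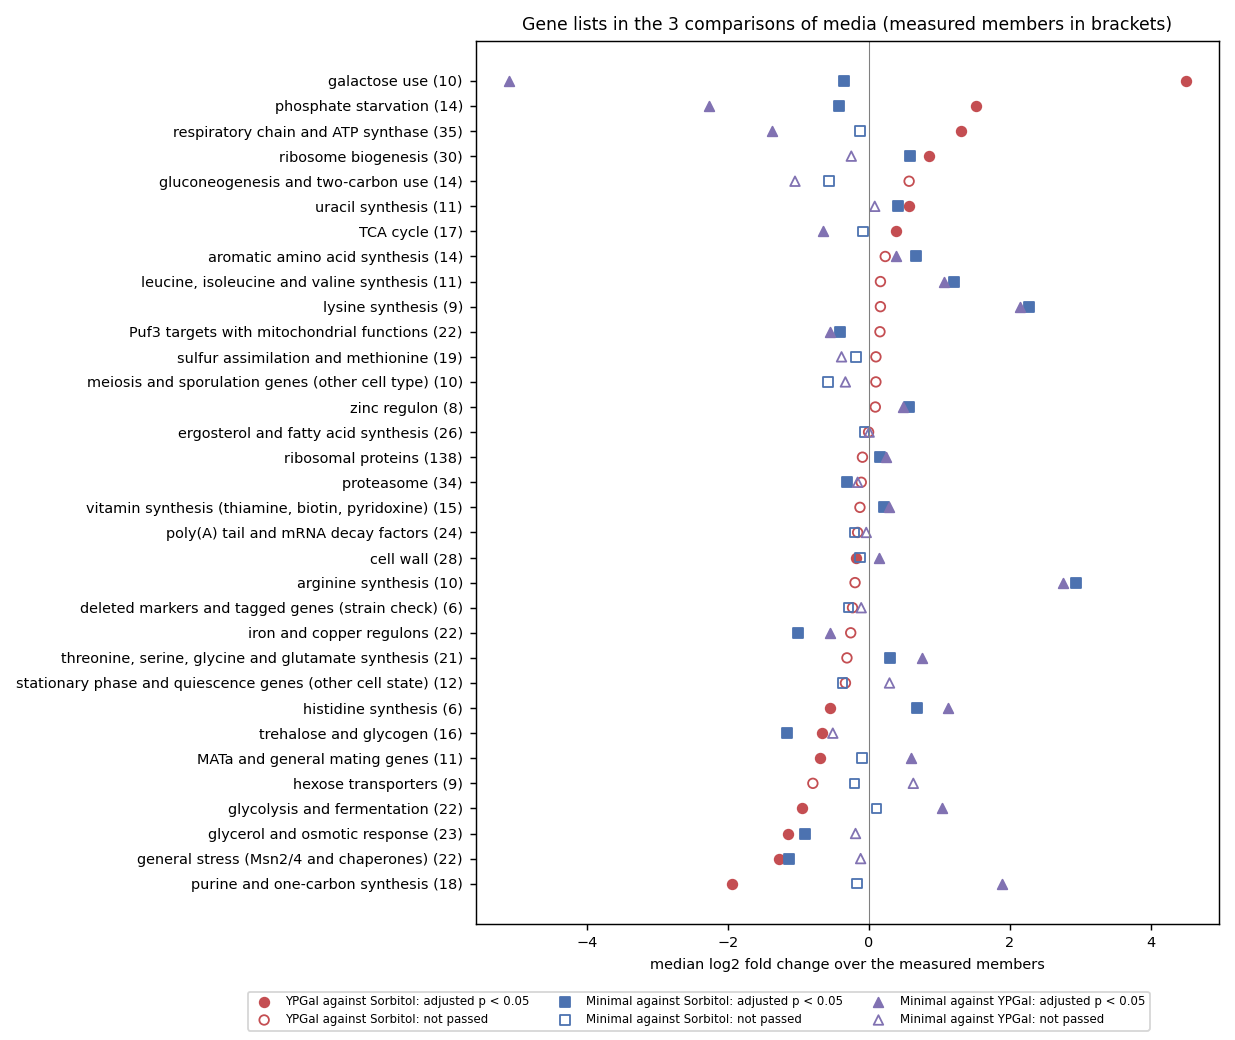
Median log2 fold change (horizontal axis) of the measured members of 33 gene lists (vertical axis, number of members in brackets) in the 3 comparisons of media; filled symbols mark lists with a camera adjusted p under 0.05 at the preset correlation. Galactose use reached 4.49 in YPGal against Sorbitol and arginine synthesis 2.94 in Minimal against Sorbitol.

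**Figure D2:**
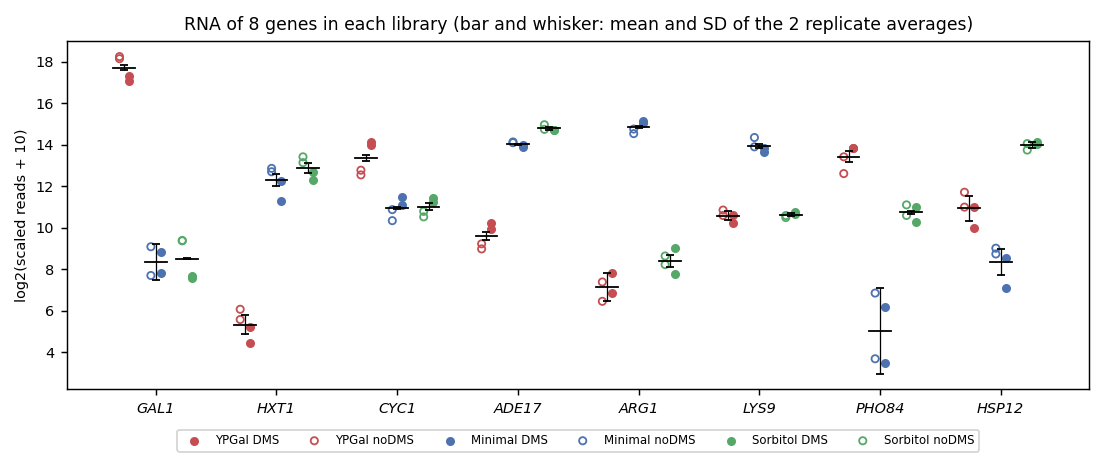
RNA of 8 genes in each of the 12 libraries, as log2 of scaled reads plus 10 (vertical axis); filled symbols are DMS and open symbols noDMS libraries, and the bar with whiskers gives the mean and SD of the 2 replicate averages per medium. GAL1 averaged 224920 scaled reads in YPGal and 422 in Sorbitol, and ARG1 30239 in Minimal and 348 in Sorbitol.

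The treatment itself was compared over all media, with medium as a block. EDC1, an activator of decapping, was higher in DMS libraries by a log2 difference of 2.16 ± 0.44 (limma adjusted p = 0.00152; SE, n = 6 libraries each), the mitochondrial carrier AGC1 by 2.15 ± 0.22, the histone chaperone VPS75 by 1.83 ± 0.15 and the cleavage factor PCF11 by 1.73 ± 0.23. The heat shock gene HSP30 fell by 4.16 ± 0.65, the regulator of glycolytic genes TYE7 by 3.23 ± 0.42 and the small nucleolar RNA SNR9 by 2.95 ± 0.23. For HSP30 the difference was -5.56 in YPGal, -1.10 in Minimal and -5.83 in Sorbitol. Its mean in DMS libraries was log2 4.78, so these sizes depend on the pseudocount of 10. Reads assigned to the tRNA genes tP(UGG)O3 and tD(GUC)G2 fell by 3.25 ± 0.41 and 2.97 ± 0.30. With limma 1596 of 5416 genes passed, 760 higher and 836 lower in DMS libraries. None of 33 lists passed (camera, smallest adjusted p = 0.0632), but for general stress genes the list median was -1.12 in YPGal, 0.25 in Minimal and -0.15 in Sorbitol. These medians differed with camera at the preset correlation in YPGal against Sorbitol (adjusted p = 3.56e-10) and Minimal against YPGal (adjusted p = 7.24e-13), but not with an estimated one (adjusted p = 0.542 and 0.478).

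**Figure D3:**
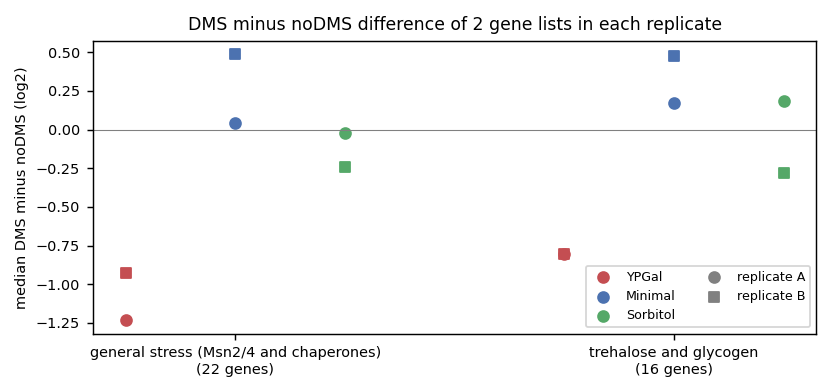
Median log2 difference between DMS and noDMS libraries (vertical axis) of the general stress list and the trehalose and glycogen list (horizontal axis) in each replicate of the 3 media. General stress medians were -1.23 and -0.92 in YPGal and between -0.24 and 0.49 in the other media.

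The base at the 5′ ends was compared to see where DMS adds stops. Shares were weighted by reads, which include PCR copies, so their size depends on that weighting. At the base just upstream of the deposited 5′ end, A and C together made up 55.6% ± 0.350 of ends in DMS and 52.2% ± 1.64 in noDMS libraries (mean and SD, n = 6 each), a difference of 3.39 percentage points (exact permutation p = 0.0185, two-sided, labels permuted within media). Without YPGal replicate A, YPGal replicate B, Minimal replicate B, Sorbitol replicate A or Sorbitol replicate B it was 3.43, 3.36, 2.71, 3.31 and 3.48 points. The exact permutation p was 0.0556 for each, which missed 0.05. Leaving out Minimal replicate A gave 4.08 points. Fewer arrangements remain when a replicate is left out, so p can rise while the difference stays similar. At the deposited 5′ end itself the difference was larger: A and C made up 75% ± 0.834 in DMS and 52.2% ± 1.23 in noDMS libraries, a difference of 22.8 points (exact permutation p = 0.00926, the smallest the 216 arrangements can give). A rose from 34.8% to 60.5%, while C went from 17.4% to 14.6%, G from 20.3% to 9.65% and U from 27.5% to 15.3%. The lowest share of A in a DMS library, 58.5%, exceeded the highest in a noDMS library, 36.4%. The shares sum to 100, so a lower share of C does not say that C gave fewer stops.

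**Figure D4:**
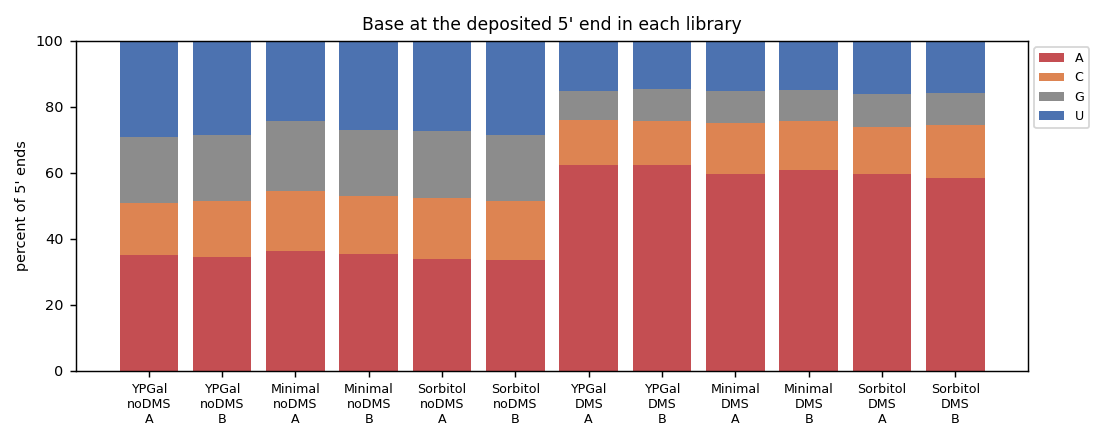
Percent of 5′ ends at A, C, G and U (vertical axis) at the deposited 5′ end in each of the 12 libraries (horizontal axis). A averaged 60.5% in DMS and 34.8% in noDMS libraries.

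Reactivity at a position was the log2 ratio of DMS to noDMS reads at an A or C, centred on the gene. In each of the 3 comparisons of media, 0 of 64706 positions in 4336 genes passed with limma, and 3546, 2809 and 4516 positions had an unadjusted p under 0.05 (5.48%, 4.34% and 6.98%) in YPGal against Sorbitol, Minimal against Sorbitol and Minimal against YPGal. No other tool was run on positions. The median SD at a position, as moderated by limma over the 3 media, was 1.35 on the log2 scale. In simulated data with limma's own spread, 0%, 1.5% and 0% of changes of log2 2 were recovered and 87.5%, 92.5% and 93.0% of changes of log2 8, and with the raw spread of each position none, so a change of log2 2 at a single base was rarely or never detectable with these data. With values as shares of the gene's total, 1 position passed in Minimal against Sorbitol, lower in Minimal.

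The mean reactivity of whole genes did not differ past the threshold either: limma gave 0 of 3267 genes in each comparison, with 285, 148 and 324 at an unadjusted p under 0.05. Some lists moved together with camera at the preset correlation. Ribosome biogenesis genes were more reactive in YPGal than in Sorbitol (median 0.56; camera adjusted p = 1.50e-05, and adjusted p = 0.751 with an estimated correlation). Trehalose and glycogen genes and general stress genes were less reactive in that comparison (medians -1.02 and -0.66; camera adjusted p = 2.33e-06 and 1.43e-05, and adjusted p = 0.203 for each with an estimated correlation). Their gene reads differed between the agents in the same directions: the medians of DMS minus noDMS were 0.27 in YPGal and -0.28 in Sorbitol for ribosome biogenesis, -1.07 and -0.14 for trehalose and glycogen, and -1.12 and -0.15 for general stress. Mean reactivity is made from the same reads, so it adds no separate evidence for these lists. Arginine genes were more reactive in Minimal than in Sorbitol (median 0.77; camera adjusted p = 0.000987, and adjusted p = 0.818 with an estimated correlation). Their RNA was scarcer in Sorbitol, by a median log2 of 2.94, and the pseudocount pulls ratios of scarce RNAs towards 0, so abundance and reactivity cannot be told apart here.

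Reactivity profiles were compared between samples by the Pearson r across the A and C positions of each gene with at least 10 of them; positions are not independent replicates. The median gene r averaged 0.288 between the 2 replicates of a medium and 0.282 between samples of different media. Within YPGal, Minimal and Sorbitol it was 0.340, 0.188 and 0.336, and over the 12 pairs between media it ran from 0.131 to 0.396. The difference of 0.0055 was smaller than the spread over pairs (SD 0.0867 within and 0.101 between media). Pairs with Minimal replicate A had 0.131 to 0.188, and the other pairs 0.2985 to 0.396. Without Minimal replicate A the difference was -0.00906. Without Minimal replicate B it was 0.0938, but this keeps the low pairs of Minimal replicate A only between media. At G and U positions, taken as a background in 1267 genes, the median gene r averaged 0.187 within and 0.163 between media. Part of the agreement at A and C is therefore not particular to the bases that DMS modifies.

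The log2 ratio of DMS to noDMS reads fell with distance from the main 3′ end of genes. Bins of 10 bases were averaged with equal weight, although bases 1 to 10 held 85 positions and bases 91 to 100 held 3279. The mean of bins over the last 100 bases exceeded that over bases past 200 and up to 300 upstream by 1.60 ± 0.942 on the log2 scale (mean and SD over 6 samples). The last 100 bases were higher in 6 of 6 samples (exact sign-flip permutation p = 0.03125, two-sided, the smallest the design allows). Samples ranged from 0.22 in Minimal replicate A to 3.11 in YPGal replicate A. At G and U positions, taken as a background, the same difference was nearly as large, 1.373 ± 0.730 (mean and SD, 6 samples). Median fragment length (5′ to 3′ end) went from 170 bases in noDMS to 122 in DMS for YPGal replicate A, which fell most. For Minimal replicate A, which fell least, it went from 151 to 153. In the other samples it was 156 to 180 in noDMS and 130 to 149 in DMS libraries. More 5′ ends near the 3′ end and shorter fragments are the same change in reads, so this fall cannot be read as base pairing. At 33 sites of the sequence that the RNA-binding protein Puf3 recognises, reactivity exceeded that of the 20 bases on each side by 0.31 ± 0.19 (mean and SD over 6 samples, 6 of 6; exact sign-flip permutation p = 0.03125, the smallest the design allows). With A positions alone it was 0.12 (exact permutation p = 0.5), with a flank of 50 bases 0.21 (exact permutation p = 0.0938) and at G and U positions 0.38 (exact permutation p = 0.0625).

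**Figure D5:**
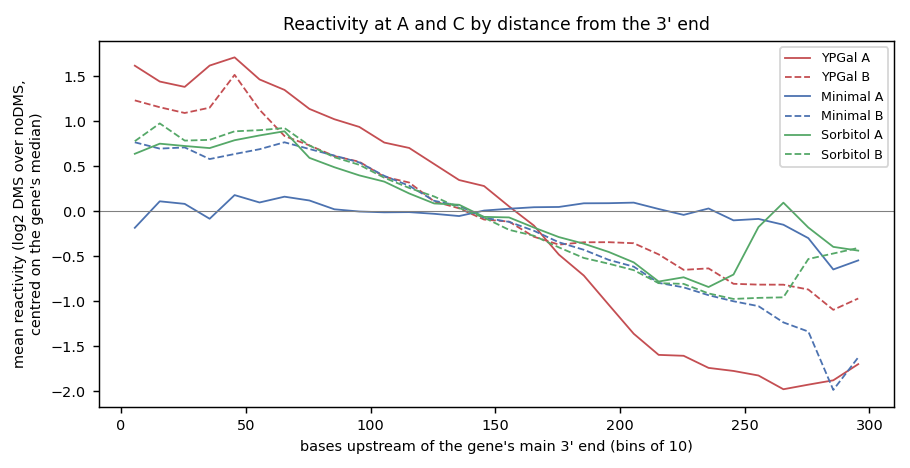
Mean reactivity at A and C (vertical axis, log2 of DMS over noDMS, centred on the gene's median) in bins of 10 bases by distance upstream of the main 3′ end (horizontal axis), a line per replicate of each medium. The difference between the mean of bins over the last 100 bases and over bases past 200 and up to 300 was 0.22 in Minimal replicate A. In the other samples it was between 1.154 and 3.11.

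The pooled profiles of single isoforms, in which the replicates are summed, were described without a test, with YPD, rich dextrose medium, beside the 3 media. The tables held 19464 isoforms in YPD, 14961 in YPGal, 14942 in Minimal and 15279 in Sorbitol, of which 9825 were shared. Net DMS reads lay on few bases: the median Gini index over A and C was 0.935, 0.960, 0.944 and 0.952 in YPD, YPGal, Minimal and Sorbitol. In 3680 isoforms with higher totals it was 0.915, 0.943, 0.920 and 0.936. The shared isoforms had a median of only 3.19 to 6.86 net reads per A or C. Low counts and negative values set to 0 raise the index, so their part was not separated. The read-weighted mean position lay 127, 125, 151 and 138 bases upstream of the poly(A) site. The same isoform in 2 media had a median r between 0.361 and 0.455. In Sorbitol, isoforms of a gene whose ends lay 1 to 5 bases apart had a median r of 0.534. For those over 100 and up to 400 bases apart it was 0.0171. In YPGal these values were 0.490 and 0.010, in Minimal 0.440 and 0.0443, and in YPD 0.392 and -0.0125. Profiles cover a fixed stretch before each 3′ end, so isoforms further apart share fewer bases. A shared base also lies at a different distance from each end, and the ratio of DMS to noDMS reads fell with that distance. The part of these effects was not separated, so the lower r cannot be read as a difference in structure between isoforms.

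Single replicates of a medium were little more alike than samples of different media: with negative values set to 0 the median isoform r averaged 0.326 within and 0.306 between media, and with them kept 0.222 and 0.209. A low r between media therefore need not be a difference between media. Among 1276 genes with at least 3 shared isoforms the median r between media was 0.399. The mean r between media was lowest in MAK11, a factor of 60S ribosome assembly, at 0.0581 over 3 isoforms, in UTP25 (0.0799), which acts in small subunit processing, in the histidyl-tRNA synthetase HTS1 (0.091), in PDB1 of pyruvate dehydrogenase (0.0943) and in the translation factor TIF35 (0.0998). These genes had 298 to 698 net reads per isoform, against 1250 to 3080 in the genes with the highest r, which were chosen after their values were seen. Those were AGC1 (0.937), DOT6, a repressor of ribosome biogenesis genes (0.936), RBG1 (0.929), the dihydroxyacetone kinase DAK1 (0.925) and FSH1 (0.923).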

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

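The tests of the explanations weighed below and the measures of S. pombe reads were chosen after the results had been seen. The difference between DMS and noDMS libraries itself differed between media, tested with limma as an interaction. In YPGal against Sorbitol 9 of 5416 genes differed (361 at an unadjusted p under 0.05), in Minimal against YPGal 22 (565) and in Minimal against Sorbitol 0 (176). TPO2, a polyamine exporter, had a log2 difference between DMS and noDMS libraries of -5.71 in YPGal, -0.59 in Minimal and -0.85 in Sorbitol. STP4 had -4.11, -1.21 and -0.78, the disaggregase HSP104 -2.74, -0.12 and -0.38, and the chaperone HSP82 -3.19, 0.42 and -0.98.

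Of 33 lists, 11 differed in YPGal against Sorbitol with camera at the preset correlation, and 9 in Minimal against YPGal, but none with an estimated correlation (smallest adjusted p = 0.542 and 0.478). In YPGal against Sorbitol the DMS minus noDMS difference was lower for general stress genes (adjusted p = 3.562e-10), trehalose and glycogen (6.471e-05), glycolysis (6.471e-05), the proteasome (0.004035), hexose transporters (0.01607) and osmotic genes (0.0215). It was higher for ribosome biogenesis (7.681e-05), ribosomal proteins (0.004606), iron and copper regulons (0.01607), gluconeogenesis (0.0215) and uracil synthesis (0.0215). In Minimal against YPGal it was higher for general stress genes (7.241e-13), trehalose and glycogen (2.545e-06), the proteasome (0.0005571), glycolysis (0.002091) and osmotic genes (0.003935). It was lower for ribosome biogenesis (0.0005384), ribosomal proteins (0.0007698), leucine, isoleucine and valine synthesis (0.01084) and uracil synthesis (0.03339).

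The general stress list was lower in DMS than in noDMS libraries of YPGal, with medians of -1.23 and -0.92 (replicates A and B, 22 genes). A loss of these RNAs under DMS in every medium is argued against by the Minimal replicates, whose lower median was 0.0447. Short fragments in the YPGal DMS libraries are argued against by Sorbitol, where DMS fragments were shorter too but the 2 medians averaged -0.131. The noDMS cultures of YPGal may have been in another state than its DMS cultures, since replicate B alone showed -0.924, but treatment and handling of a culture cannot be told apart here. A response of living cells to DMS that differs between media stays open and untested.

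The share of S. pombe reads, which no comparison above uses, was higher in DMS than in noDMS libraries by 1.47-fold (6 of 6 pairs; exact permutation p = 0.00926). Its difference between media did not pass (exact permutation p = 0.0667, which 90 arrangements cannot bring lower, so the test could not pass). Geometric means were 2.27% in YPGal, 1.29% in Minimal and 0.380% in Sorbitol. Repeated counting of PCR copies stays open as the cause of the DMS part. On distinct end pairs the lowest of the 6 ratios was 1.149, but shares of distinct pairs also depend on depth. Depth differed within pairs, with 27627022 DMS and 8864664 noDMS reads in Minimal replicate A. Misplaced S. cerevisiae reads stay open: at most 7.60% of S. pombe reads in a library lay at its 10 highest 3′ ends, but S. cerevisiae reads are spread widely too. The share in YPGal was 5.97 times that in Sorbitol, but 2.93 times on distinct end pairs, and it may reflect different amounts of S. cerevisiae RNA per S. pombe cell, which cannot be told apart from unequal mixing because the labels give no cell numbers.

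In 1 of 6 groups tested for a sample far from the others, the share of A and C just upstream of the deposited 5′ end in noDMS libraries, Minimal replicate A stood apart at 55.4%, with a gap of 0.7149 of the range. Chance flags about 1 in 20 groups.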

How the results depend on the processing

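The tests on distinct end pairs, with the base next upstream as the modified base, with centring on distance, in genes with at least 5 tested positions, with each position of the deposited 5′ end counted once, with Minimal profiles as deposited, and at G and U for profiles, distance and Puf3 sites were chosen after the data were seen, as were all those of 3′ UTR length. The others were planned, except that the windows of the distance test were set after their values were seen. Of 170 alternative values of counts, lists and shares, 142 kept direction and side of the threshold, or stayed within 1.5 times or the spread. These 142 include counts of positions that were 0 as in the main fit. In simulated data with the raw spread the position test recovered 0% of changes, so agreement at 0 shows no stability. Of 5968 values for 340 pairs of a named gene and a comparison 5408 were kept, with 557 no longer past the threshold and 3 turned. With the noDMS libraries alone HXT4 had 0.064 in YPGal against Sorbitol and HSP42 -0.68 in Minimal against YPGal, and with the DMS libraries alone RIP1 had -0.19 in Minimal against Sorbitol; none of these 3 passed, and the cause was not tested. Counts of genes in YPGal against Sorbitol, Minimal against Sorbitol and Minimal against YPGal were 305, 253 and 455 with the noDMS libraries alone, where fewer libraries are averaged, and 245 in Minimal against Sorbitol with the DMS libraries alone. Leaving out each replicate gave 333 to 798, 204 to 620 and 388 to 875 genes, 1155 to 1696 for DMS against noDMS, 2.71 to 4.08 points for A and C just upstream of the 5′ end, and -0.0224 to 0.0938 for the gap in r between profiles within and between media. The lone sample is then assumed to vary like the other groups. With a replicate block 995, 615 and 943 genes passed, and 1587 for DMS against noDMS, with edgeR 811, 419 and 672, with DESeq2 1069, 629 and 932, and on distinct end pairs 1074, 682 and 878. With an estimated correlation 1, 0 and 7 lists passed in place of 14, 19 and 19. In Minimal against Sorbitol 1 position passed with shares of the gene's total. The mean r of profiles within media was 0.507 for linear differences, 0.496 at a position minimum of 100 and 0.187 at G and U. The mean r of isoforms between the 3 media was 0.550 over the last 100 bases, 0.616 for isoforms with 10 times the minimum and 0.328 with negative values kept. Puf3 sites differed by 0.21 with a flank of 50, 0.12 with A only and 0.38 at G and U, none past the threshold, and C only gave no value. The S. pombe share in YPGal was 2.93 times that in Sorbitol on distinct end pairs. The causes of these changes were not tested. Depth limited which positions could be tested, 169020 at a minimum of 5 scaled reads, 64706 at the minimum used and 15505 at a minimum of 100.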

Other observations

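The tests of explanations in this part, the 3′ UTR lengths and the half-lives were chosen after the data were seen. Several lists not described above also moved with camera at the preset correlation. In Minimal against Sorbitol ribosomal protein genes were higher as a list, although only 3 of 138 rose (2 adjusted over the list alone; median 0.15; camera adjusted p = 1.5e-07, and adjusted p = 0.206 with an estimated correlation), among them RPS9A by 1.06 ± 0.22 (SE, n = 2 per medium). Proteasome genes were lower as a list with 0 of 34 past the threshold of limma (median -0.31; camera adjusted p = 0.00153, and adjusted p = 0.546 with an estimated correlation). Of 22 mitochondrial targets of Puf3 2 fell, COX17 by 1.23 ± 0.28 and COX23 by 1.10 ± 0.32, both of cytochrome oxidase assembly (median -0.42; camera adjusted p = 0.00917, and adjusted p = 0.462 with an estimated correlation). Of 11 uracil genes 2 rose, URA1 by 1.96 ± 0.22 and URA4 by 0.94 ± 0.22 (4 adjusted over the list alone; median 0.41; camera adjusted p = 0.00029, and adjusted p = 0.187 with an estimated correlation).

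In YPGal against Sorbitol histidine genes fell, 3 of 6 with 3 not passed (4 adjusted over the list alone; median -0.55; camera adjusted p = 0.00205, and adjusted p = 0.29 with an estimated correlation), HIS4 by 2.06 ± 0.20 and HIS5 by 1.86 ± 0.22. The uracil permease FUR4 rose by 2.47 ± 0.35 (SE, n = 2 per medium). Outside lists that passed, MMP1, a permease of S-methylmethionine, rose by 3.51 ± 0.27. In Minimal against YPGal 7 of 11 genes of leucine, isoleucine and valine synthesis rose (7 adjusted over the list alone; median 1.06; camera adjusted p = 2.68e-08, and adjusted p = 0.108 with an estimated correlation), such as BAT1 by 1.58 ± 0.19, and CTR1 and FIT3 of the iron and copper regulons fell by 3.21 ± 0.21 and 3.11 ± 0.20. For CTR1 the difference was -4.38 in the noDMS and -2.03 in the DMS libraries (limma interaction adjusted p = 0.00513).

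The strain's labels give HIS3 as deleted, yet reads assigned to HIS3 averaged 3783 ± 1611 scaled reads (SD over 12 libraries, lowest 1499), and 5′ ends that each held over 1% of them lay up to 159 bases upstream of the end of its reading frame. HIS3 rose in Minimal by 0.83 ± 0.18 against Sorbitol and by 1.35 ± 0.18 against YPGal (limma, SE, n = 2 per medium). LEU2, MET17 and URA3 were not analysed here. RPO21, whose product carries a tag, had 51.8 ± 47.6 scaled reads, RPL13A 475 and its paralog RPL13B 63548. The mating-type genes of the labelled MATa strain were present, with MFA1 at 18798, MFA2 at 23232 and the receptor STE2 at 10509 scaled reads.

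Length of the 3′ UTR, averaged over the isoforms of each of 4863 genes, differed past the threshold of limma in 1 gene: the 3′ UTR of YDR132C was 124 bases in Minimal and 170 in Sorbitol, a difference of -45.5 bases (adjusted p = 0.0384). With a replicate block, and with the noDMS libraries alone, 0 genes passed, although in the latter the difference of YDR132C was -70.5 bases. In YPGal against Sorbitol and in Minimal against YPGal limma gave 0 genes, with 611 and 655 at an unadjusted p under 0.05 and median differences of -0.59 and 0.93 bases.

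The gap in median r between profiles within and between media was 0.0055, smaller than its spread over pairs, but 0.0938 without Minimal replicate B. Leaving out that sample keeps the low r of Minimal replicate A only in pairs between media, which raises the gap. The Minimal replicate A sample alone is argued against as the reason for the small gap, since without it the gap was -0.00906. Low counts per position could hide a difference: at a position minimum of 100 the gap was 0.0204, with an SD over pairs of 0.168 between media, which leaves this open. No biological explanation was tested.

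The half-lives that the authors give for isoforms rose weakly with the Gini index of the profile across 5613 isoforms, with a Spearman rho of 0.203 in YPD, 0.156 in YPGal, 0.145 in Minimal and 0.0569 in Sorbitol. Isoforms are not independent replicates. Within genes, over 4126 isoforms, rho was 0.0256 in YPD, -0.017 in YPGal, 0.0152 in Minimal and -0.0038 in Sorbitol. No relation of half-life with the Gini index was thus seen between isoforms of a gene. Noise could hide one, since shared isoforms had a median of only 3.19 to 6.86 net reads per A or C. In YPGal the Gini index was 0.943 in isoforms with higher totals, against 0.960 over all shared isoforms, and abundance was not held fixed. For the read-weighted mean position upstream of the poly(A) site, rho with half-life within genes was weakly negative. It was -0.0441 in YPD, -0.067 in YPGal, -0.0752 in Minimal and -0.0792 in Sorbitol, and its cause was not tested.

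For DMS against noDMS, where 1596 genes passed, 1 of 100 splits of the 12 libraries within media gave as many, which was the real split. The highest of the others gave 562. With 100 of 108 possible splits counted, chance is unlikely but not excluded.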
